A study of Mus musculus with 16 samples.

How the data were processed

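Chromatin immunoprecipitation sequencing (ChIP-seq) was carried out on cultured mouse muscle stem cells (satellite cells) from the hindlimb of C57BL/6 animals. Cells had been exposed for 48 h to small interfering RNA, per the labels' protocols; the labels name LncMyoD, a long noncoding RNA transcribed upstream of Myod1, as the target, and mark each library as control or knockdown. The treatment text, which names LncMyoD as the target, is the same for every sample, controls included, so a library is called control here from its title and genotype label alone, and what the control cells received is not given in the sources used here. Antibodies against H3K27ac, a histone acetylation of active promoters and enhancers, and against the myogenic transcription factor MyoD were each used on 2 control and 2 knockdown libraries, giving 8 ChIP libraries. The remaining 8 of the 16 samples are input libraries, which were not analysed here. Libraries were made by tagmentation of antibody-bound chromatin and sequenced as read pairs, per the labels' protocols.

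For each ChIP library 1 peak list was used, called separately for each library and not on pooled replicates. The submitters' processing notes name the mm10 build with Bowtie2 2.3.2, Picard 2.9.2, SAMtools 1.3, MACS2 2.1.1 and bedtools 2.26.0. The options of these tools, and which input was set against which library, are not given in the sources used here. Each deposited peak carries a fold enrichment over background at its summit, a linear ratio made by the authors' peak caller. The deposited lists also give −log10 of the p-value and −log10 of the q-value of each peak, and a whole-number score that the authors' caller derives from the q-value. No deposited peak had a −log10 q below 1.30. A fold enrichment belongs to its own list, so it was used here to describe, rank and filter peaks within a list. Fold values were not themselves tested between libraries. Peak numbers were also compared between groups after a cut at a fold of at least 5. That cut does not ask for the same signal in each list.

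The lists hold no read counts, so the depth of each library is unknown, and the intervals given for shares and odds ratios cover counting error over regions only. An indirect value related to depth was read from the fold enrichments, which lay on whole multiples of a library-specific step (tolerance 0.2% of a step). If a fold is the pileup plus 1 over the background plus 1, the default form in MACS2, the step gives the background pileup. In 7 libraries at least 75.7% of the values were whole steps. In the H3K27ac knockdown 2 library only 2.84% were, so no value was taken from it.

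The peaks of the 4 libraries of an antibody were merged into regions wherever they overlapped or touched (merge gap 0 bp), with at least 1 shared base counting as presence. A control-only region held a peak of both control libraries and of neither knockdown library, and a knockdown-only region the reverse. Their numbers were set beside those of the other 2 ways of splitting 4 libraries into pairs. Peak numbers were compared by the two-sided exact permutation test over the 6 assignments of 4 libraries, whose smallest possible p is 0.333. This exact test could therefore not reach 0.05. The labels do not say whether replicates came from separate animals or cultures, so the spread between them may be technical. Fisher's exact test and random gene lists treat regions and genes as the units and describe these libraries.

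Regions on chromosomes 1 to 19 and X were assigned to a gene body that they overlapped. Outside genes the nearest gene body within 50 kb was taken. Of several overlapped genes the one with the nearest end was used, and ties went to the first symbol in alphabetical order. A region that spans several genes therefore does not carry the names of all of them. The genes were the 21628 protein-coding or listed genes of the RefSeq table of GRCm38.p6, the assembly that mm10 represents. All 320 genes of the fixed lists matched this table by symbol. The table gives the start and end of each gene without strand, exons or untranslated regions. The planned distance to the transcription start site was therefore replaced by the distance to the gene body, and the planned promoter share by the share of regions within 1 kb of either annotated gene end. The planned search for E-box motifs at MyoD summits, with its 3 alternatives, was not run because no genome sequence was used here.

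The 15 sets of genes (10 functional lists and 5 lists of markers of other cell types) were fixed. The net share of a list was its control-only minus its knockdown-only regions as a percentage of its regions. It was compared with 10000 random gene lists matched on regions per gene by a two-sided permutation test, with Benjamini-Hochberg adjustment over the 15 lists of an antibody. Joint loss was the odds ratio that a MyoD region lost in both knockdown libraries, against one kept in all 4, overlapped a control-only H3K27ac region rather than one present in all 4. It was also computed over 5 strata of fold enrichment (Mantel-Haenszel).

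Named genes followed a rule: all regions within 100 kb of Myod1; the 10 group-only regions of each antibody and direction with the highest mean fold enrichment that were assigned to a gene; up to 4 members of each list with the most group-only regions; and Myog, Mymk, Mymx, Acta1, Ckm, Myh3, Pax7 and Myf5 in every case. Some items that the rule names are not reported here. Any other gene named was chosen after its values were seen. The groups, gene lists, naming rule, tests and all alternatives, except those named in the closing section, were set before the data were examined.

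The alternatives were stricter peaks (−log10 q of at least 5) in all libraries or in the group alone, a fold enrichment of at least 5, equal numbers of peaks per library, merging within 1000 bp, an overlap of at least 50% of the shorter peak, other windows around genes, a replicate block and leaving out each library in turn. The list test was tested on simulated data: with 25-gene lists in which control-only regions were 5 times as frequent as in all genes, 79% of 100 lists had p under 0.05 among 13223 genes with H3K27ac regions and 98% among 8660 genes with MyoD regions. With no planted change 1% and 6% did. At 3 times the frequency the shares were 46% and 64%. These shares count unadjusted p-values of single lists of 25 genes drawn from genes with regions. They do not give detection rates after the Benjamini-Hochberg adjustment by which lists were called, nor for smaller lists. The MyoD list of immune markers, for example, had 6 genes with regions and 11 regions. Merged regions were checked against bedtools 2.31.1. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.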

Results

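H3K27ac and MyoD binding were profiled by ChIP-seq in cultured mouse satellite cells, the stem cells of skeletal muscle, after knockdown of the long noncoding RNA LncMyoD and in control cells, with 2 libraries per group and antibody. The H3K27ac lists held 46259 and 53048 peaks in the control libraries and 54082 and 39964 in the knockdown libraries, covering 37.6 to 57.5 Mb. The MyoD lists held 17818 and 17649 peaks in the controls and 16524 and 13146 in the knockdown, covering 4.70 to 6.90 Mb. Median peak widths were 562 to 639 bp for H3K27ac and 322 to 353 bp for MyoD. Read depth is unknown. RNA was not measured in these libraries, so the depletion of LncMyoD itself was not checked.

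**Figure D1:**
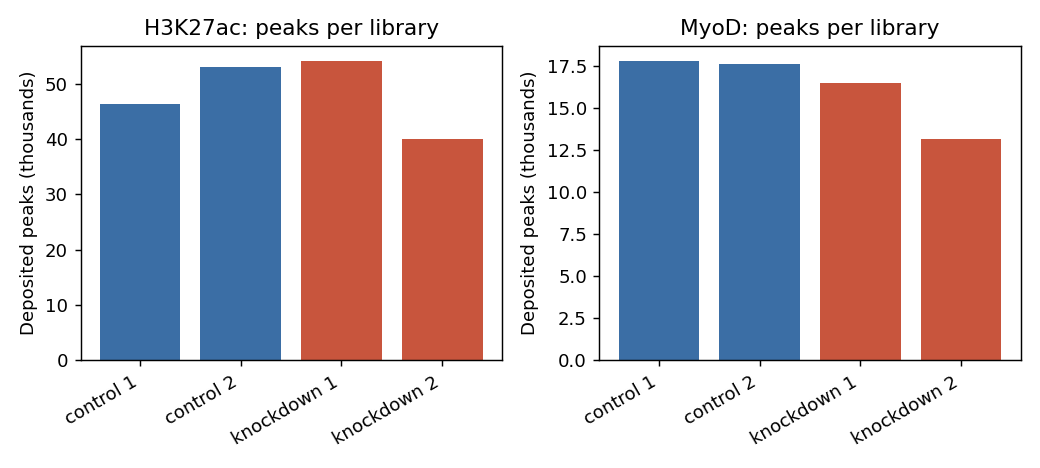
Bars show the number of deposited peaks (vertical axis, in units of 1000) in each library, with H3K27ac on the left and MyoD on the right, control libraries in blue and knockdown libraries in red. The H3K27ac knockdown libraries, at 54082 and 39964 peaks, lie on either side of both controls, while both MyoD knockdown libraries, at 16524 and 13146, lie below the controls.

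LncMyoD is encoded upstream of Myod1, so the Myod1 locus (mm10 chromosome 7, 46376474 to 46379092) was examined first. MyoD itself occupied this locus in both groups: of 14 MyoD regions within 100 kb of the gene, 10 were present in all 4 libraries and 0 were control-only or knockdown-only. The MyoD regions starting at 46283631, 46347696 and 46431456 lacked a peak only in knockdown 2, the library with the fewest MyoD peaks. The region starting at 46371079 lacked a peak only in control 2. The region over the Myod1 start (46376050 to 46376699) had fold enrichments of 5.62 and 6.95 in the controls and 6.53 and 6.27 in the knockdown. The region 22.6 kb from this end of the gene (46353040 to 46353844) had values of 16.5 and 21.2 in the controls and 19.9 and 10.2 in the knockdown. Regions at 27.1 kb, 25.9 kb and 10.1 kb on the same side were also present in all 4 libraries. Of 21 H3K27ac regions in the same window, 8 were present in all 4 libraries and 0 were group-only. They included a region of 6224 bp over Myod1 (46374547 to 46380770) and a region of 7665 bp at 46346942 to 46354606 that contained 4 of the MyoD regions. The H3K27ac regions present in 3 libraries, starting at 46300701, 46365400, 46366050 and 46380907, all lacked a peak in knockdown 2.

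**Figure D2:**
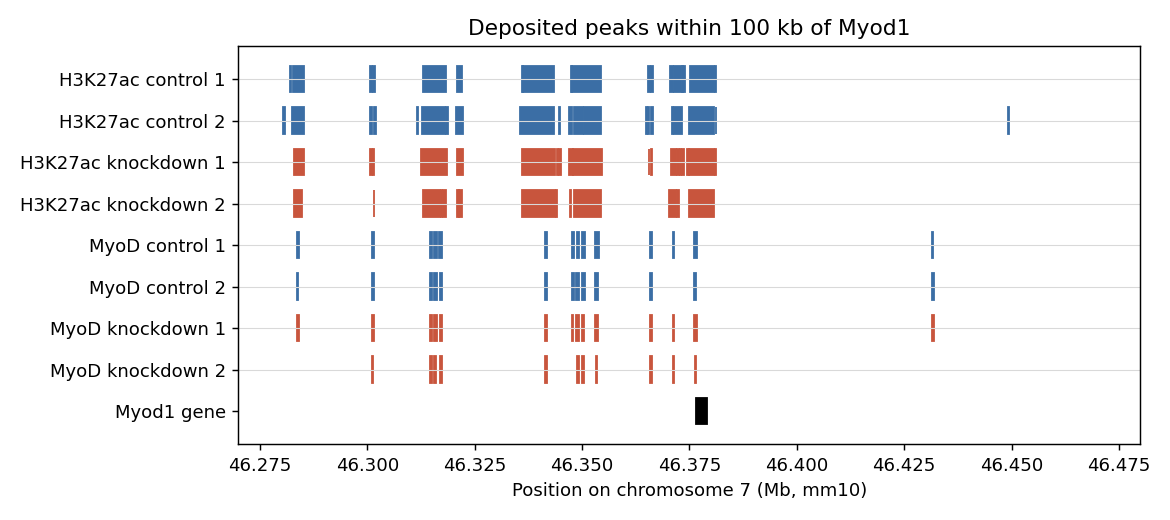
Each block is a deposited peak within 100 kb of Myod1, drawn to scale along chromosome 7 (horizontal axis, Mb, mm10) with a line per library, controls in blue and knockdown in red; the gene is in black. Of the regions formed by these peaks, 8 of 21 for H3K27ac and 10 of 14 for MyoD were present in all 4 libraries.

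Among genes of myogenic differentiation, Myog, Mymk, Mymx, Acta1 and Myh3 carried peaks of both antibodies within 1 kb of a gene end in all 4 libraries. At Myog, the myogenin gene, the MyoD fold enrichment was 16.9 and 11.6 in the controls and 5.05 and 10.97 in the knockdown, and the highest H3K27ac value was 10.6 and 9.79 against 11.3 and 8.03. Mymk and Mymx encode the muscle fusion proteins myomaker and myomixer, and the MyoD value at Mymx was 16.5 and 7.62 in the controls and 11.8 and 11.9 in the knockdown. Of 6 MyoD regions at Acta1, skeletal α-actin, 4 were present in every library, as were all 5 at Myh3, embryonic myosin heavy chain. Pax7, the satellite cell transcription factor, had 46 H3K27ac regions, with a peak near a gene end in 4 of 4 libraries, and 9 MyoD regions, of which 3 were present in all libraries and 0 lay near a gene end. Myf5 had 1 H3K27ac region, present in all 4 libraries, and 1 MyoD region, present in control 2 and knockdown 1. No region of either antibody was assigned to Ckm, muscle creatine kinase.

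The series was designed to ask how H3K27ac is distributed after LncMyoD knockdown. Of 60038 H3K27ac regions, 26130 were present in all 4 libraries, 874 were control-only and 461 were knockdown-only. The control-only region with the highest mean fold enrichment lay inside Nup133, a nuclear pore gene (chromosome 8, 123907257 to 123907662; 5.58 and 7.40). It was followed by regions near the importin gene Ipo8 (chromosome 6, 148760762 to 148761294; 5.95 and 4.91) and 19.4 kb from Snai1, a transcriptional repressor of epithelial genes (chromosome 2, 167562252 to 167562918; 5.39 and 5.33). Control-only regions inside Ip6k3, Ascc1, Galnt18 and Kif24, and near Zwint, Acta2 and Dyrk3, had mean values of 4.89 to 5.14. Acta2 encodes smooth muscle α-actin, and its region lay 7.002 kb from the gene.

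Among knockdown-only H3K27ac regions, the highest mean fold enrichment was 3.99 kb from Cenpa, the centromeric histone H3 variant (chromosome 5, 30678827 to 30679786; 8.19 and 5.005). Regions near Ccdc54 (chromosome 16, 50600889 to 50601242; 5.82 and 5.74) and inside Synpo2, which encodes an actin-binding protein of the Z-disc (chromosome 3, 123143687 to 123144291; 6.53 and 4.97), came next. Knockdown-only regions near Fbxo28, Rab11fip2, Uvrag, Dars and Cdk18 and inside Nos1, neuronal nitric oxide synthase, and Gcfc2 had mean values of 5.23 to 5.55. With a −log10 q of at least 5 required in all libraries, the regions of Fbxo28, Uvrag, Nos1 and Gcfc2 were no longer knockdown-only. When peaks within 1000 bp were merged, those of Nup133, Zwint, Dyrk3, Ccdc54, Synpo2 and Cdk18 were no longer specific to a group.

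Group-only H3K27ac regions were weakly enriched. The median of their mean fold was 3.50 in control-only and 3.86 in knockdown-only regions, against 7.56 in regions of all 4 libraries. Of the 12876 regions in the upper 2 quintiles of control fold enrichment, 0 lacked a peak in both knockdown libraries, which allows a share of up to 0.0233%. Of control-only regions 8.71% lay within 1 kb of a gene end, against 7.81% of knockdown-only regions (Fisher's exact p = 0.605) and 34.3% of regions in all 4 libraries. With a library left out, regions of 1 library were set against regions shared by 2, which are unlike sets, and the difference was −4.39 percentage points without control 1, 3.51 without control 2, 12.4 without knockdown 1 and −1.30 without knockdown 2.

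The numbers of group-only H3K27ac regions were smaller than those of 2 of the 4 mixed pairs of libraries. Control 1 and knockdown 1 alone shared 2200 regions, and control 2 and knockdown 1 alone shared 3633. Mean peak number was 49653.5 ± 4800.55 (SD, n = 2) in controls and 47023 ± 9982.93 (SD, n = 2) in the knockdown, a difference of −2630.5 that was smaller than the spread between knockdown libraries (exact permutation p = 1). Overlap by covered bases (Jaccard index) was 69.0% between the controls, 61.0% between the knockdown libraries and 62.4% to 70.3% between groups. With equal numbers of peaks per library, 757 regions were control-only and 712 knockdown-only.

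**Figure D3:**
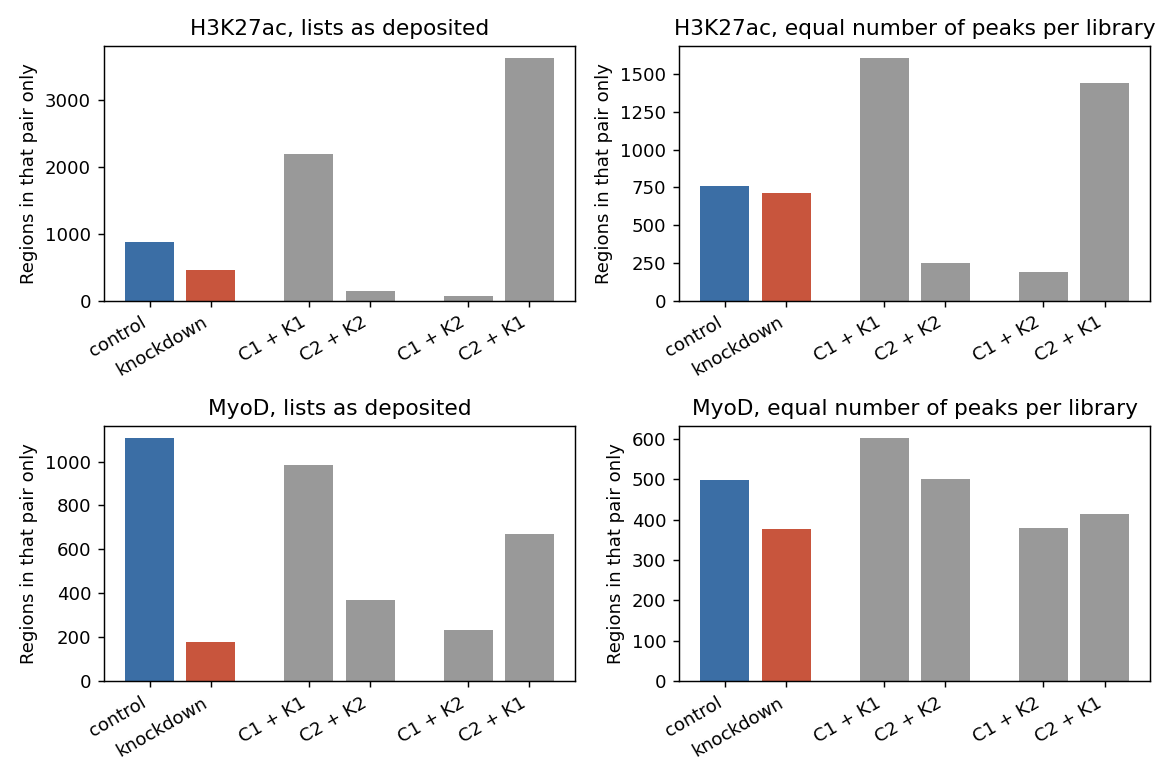
Bars count the regions (vertical axis) held by both libraries of a pair and by neither of the other 2, for H3K27ac (top) and MyoD (bottom), with lists as deposited (left) and equal numbers of peaks per library (right); C is control, K is knockdown, and gray bars mix the groups. For H3K27ac the tallest bar as deposited is the mixed pair C2 + K1 at 3633, and for MyoD with equal numbers it is C1 + K1 at 602.

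By gene list, the satellite cell and quiescence genes had 10 control-only and 2 knockdown-only H3K27ac regions of 343. Pax7 held 3 of the control-only regions, Foxo3 held 2 and the chemokine receptor gene Cxcr4 held 1, while Fgfr1 held 1 of each kind. Extracellular matrix and TGF-β genes had 7 and 1 of 297, with 2 control-only regions at Col3a1 (type III collagen), 1 each at Lama2 and Smad7, and 1 of each kind at Lamc1. Myogenic regulators had 5 and 3 of 269, with 2 control-only regions each at Celf2 and at Fst (follistatin), 1 at Pitx3, and knockdown-only regions at Tcf12, Myog and Eya4. Sarcomere genes had 4 and 0 of 180, at Unc45b, Actc1, Myot and Myl4. Excitation-contraction coupling genes had 3 and 0 of 135, among them regions at Cacna2d1 and Jph2. Fusion and neuromuscular junction genes had 2 and 3 of 151, with control-only regions at Mymk and Itga7 and knockdown-only regions at Myof, which held 2, and Dok7. Genes of the IMP-IGF axis had 5 and 1 of 151, of which Igf1r (the IGF1 receptor) held 3 control-only regions, Irs2 and Akt2 held 1 each, and Igf2bp2 the knockdown-only region. Cell cycle genes had 2 and 0 of 113, both at the replication helicase gene Mcm2, and AP-1 and immediate early genes had 0 and 1 of 73, at Atf3. Housekeeping genes had 0 and 0 of 61.

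Markers of other cell types were counted in the same way. Fibro-adipogenic markers had 0 control-only and 2 knockdown-only regions of 43, at Dpt and Cebpa, endothelial markers 2 and 1 of 31, at Cdh5, Egfl7 and Erg, and smooth muscle markers 1 and 0 of 43, at Acta2. Immune markers had 0 and 0 of 14, and Schwann and neural markers 0 and 0 of 35. In the permutation test against matched random lists, 0 of the 15 lists passed after Benjamini-Hochberg adjustment and 1 had an unadjusted p under 0.05. This was the fibro-adipogenic list, with a net share of −4.65% (permutation p = 0.0282, adjusted p = 0.423) against 0.688% over all genes. With equal numbers of peaks per library the direction of this list turned, at 7.41% (permutation p = 0.0668), and with stricter peaks its net share was 0%.

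For MyoD, the comparison asks whether its binding sites differ after LncMyoD knockdown. Of 24420 MyoD regions, 9958 were present in all 4 libraries, 1106 were control-only and 177 were knockdown-only. The control-only regions with the highest mean fold enrichment lay 6.03 kb from Rsph3a (chromosome 17, 7985591 to 7985979; 7.27 and 10.3) and inside Pakap (chromosome 4, 57611232 to 57611611; 9.58 and 7.95). Another lay 0.033 kb from Mcam, a cell adhesion gene of pericytes and endothelium (chromosome 9, 44134268 to 44134624; 7.14 and 7.95). Those of Gm51965, Cd300c, D830031N03Rik, Cdk5rap2, Gpd1l and Ramp2 had mean values of 7.44 to 7.77.

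Knockdown-only MyoD regions were led by sites inside the ubiquitin ligase gene Ube3b (chromosome 5, 114405054 to 114405578; 7.21 and 8.60) and inside Nfib, a nuclear factor I gene (chromosome 4, 82360229 to 82360706; 7.74 and 7.05). Sites inside Gatad2a, Zbtb2, Prkcb, Nol4 and Osbpl9 and near Tnc (tenascin C), Try4 and Ryk had mean values of 6.23 to 6.98. The regions of Prkcb and Ryk were no longer knockdown-only with a −log10 q of at least 5 required in all libraries, nor that of Osbpl9 when peaks within 1000 bp were merged.

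MyoD regions without a peak in the knockdown libraries were mostly those of low enrichment. Of regions present in both controls, 8.02% of 13798 had no peak in either knockdown library, but by quintile of control fold enrichment the share was 26.4%, 11.6%, 1.99%, 0.109% and 0% from the lowest to the highest. In the upper 2 quintiles 3 of 5519 regions were missing (0.0544%, 95% Clopper-Pearson interval 0.0112% to 0.159%). For the pair of control 1 and knockdown 1 against the others, 4 of 5337 were missing. A peak far above the caller's threshold can lose signal and still be called, so these shares bear on complete loss of a peak and not on the level of binding. The median of the mean fold was 5.13 in control-only and 5.31 in knockdown-only regions, against 8.34 in regions of all 4 libraries.

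**Figure D4:**
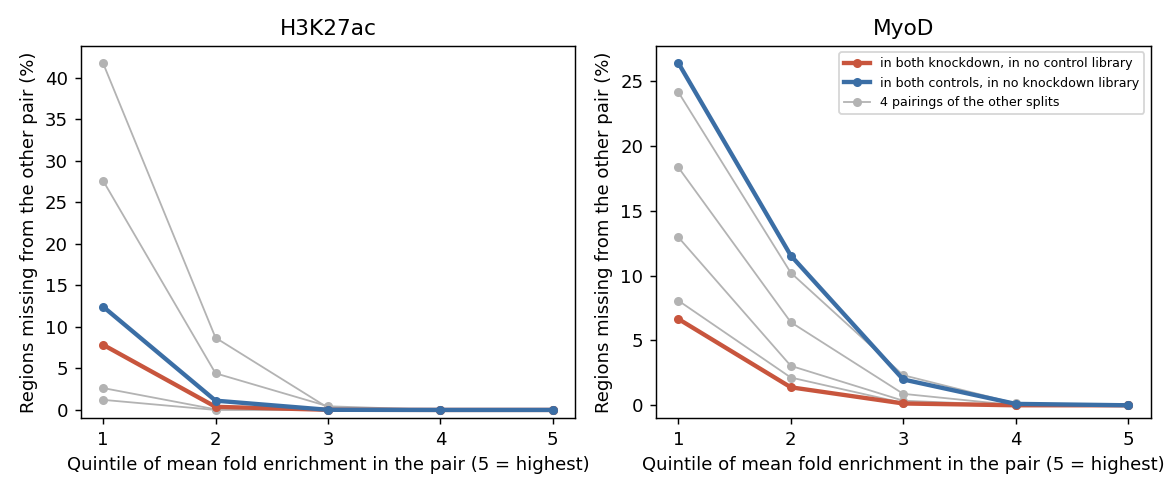
Lines show the share of regions present in both libraries of a pair that had no peak in the other 2 (vertical axis, %), by quintile of mean fold enrichment in the pair (horizontal axis, 5 = highest), for H3K27ac (left) and MyoD (right); blue is control against knockdown, red the reverse, and gray the 4 pairings that mix the groups. For MyoD the blue line starts at 26.4% in the lowest quintile and reaches 0% in the highest.

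Control-only MyoD regions lay within 1 kb of a gene end more often than knockdown-only regions, at 17.8% (196 of 1104) against 7.91% (14 of 177), with 13.0% in regions of all 4 libraries (odds ratio 2.51, Fisher's exact p = 0.000638, Benjamini-Hochberg adjusted p = 0.00128 over the 2 antibodies). Fisher's test here takes regions as units, so its p-value leaves out variation between libraries. Mcam, Gpd1l, D830031N03Rik and Ramp2 were among the genes with such a control-only site. The share also differed between the knockdown libraries: regions of a control paired with knockdown 1 alone stood at 10.9% and 9.88%, those of a control paired with knockdown 2 alone at 14.2% and 15.2%, and regions of both controls and knockdown 2 at 18.5%. The difference of 9.84 percentage points was 2.79 without control 2 and 3.47 without control 1, where regions of 1 control library were set against regions shared by both knockdown libraries, which are unlike sets.

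Mean MyoD peak number was 17733.5 ± 119.501 (SD, n = 2) in controls and 14835 ± 2388.61 (SD, n = 2) in the knockdown, 16.3% lower (exact permutation p = 0.333, the smallest this design allows), and the difference of −2898.5 was −942.5 among peaks with a fold enrichment of at least 5 (exact permutation p = 0.667). The background pileup implied by the fold enrichments was 19.3% lower in the knockdown, at 1.63 against 2.02. With a lower background, a fold of 5 takes a lower pileup. If lower depth had reduced the pileup at sites as well, the cut would not be easier to pass in the knockdown lists. Which of these applies is unknown, as the lists hold no read counts. With equal numbers of peaks per library 498 regions were control-only and 378 knockdown-only, whereas control 1 and knockdown 1 alone shared 602. With 1 knockdown library left out, a knockdown-only region needs a peak in 1 library and a control-only region in 2, and the counts were 1778 control-only and 2032 knockdown-only regions without knockdown 2 and 3172 and 1112 without knockdown 1. Overlap by covered bases was 58.4% between the controls, 52.6% between the knockdown libraries and 51.8% to 58.2% between groups.

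By gene list, satellite cell genes had 8 control-only and 1 knockdown-only MyoD regions of 116. Cxcr4 held 2 of the control-only regions, the Notch pathway genes Notch2 and Heyl held 1 each, and the collagen gene Col5a1 held 1 of each kind. Myogenic regulators had 6 and 0 of 89, of which Rbm24, an RNA-binding regulator of muscle splicing, held 2, and Fst, Eya4 and Tcf4 held 1 each. Extracellular matrix and TGF-β genes had 5 and 0 of 103, with sites at Loxl2, Col1a2, Lama5 and Smad3. Fusion and neuromuscular junction genes had 4 and 0 of 70, at Cdh2 (N-cadherin), Dysf (dysferlin), Myof and Musk, the kinase of the neuromuscular synapse. Genes of the IMP-IGF axis had 4 and 0 of 59, at Akt2, Igf1, Mycn and Akt1. Sarcomere genes had 3 and 0 of 99, at the tropomyosin genes Tpm2 and Tpm1 and at Neb (nebulin). Excitation-contraction coupling genes had 3 and 0 of 62, at the junctophilin genes Jph2 and Jph1 and at Cacnb1. AP-1 genes had 1 and 0 of 25, at Junb, cell cycle genes 0 and 0 of 32, and housekeeping genes 0 and 0 of 12.

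Markers of other cell types also held control-only MyoD regions. Smooth muscle and pericyte markers had 3 and 0 of 20, at Mcam, Tagln (transgelin) and Abcc9, endothelial markers 2 and 0 of 24, at Tek and Eng, fibro-adipogenic markers 1 and 0 of 15, at Gsn, Schwann markers 1 and 0 of 13, at Pmp22, and immune markers 0 and 0 of 11. In the permutation test 0 of the 15 lists passed after Benjamini-Hochberg adjustment, and 0 had an unadjusted p under 0.05. The nearest was the smooth muscle and pericyte list, with a net share of 15.0% (permutation p = 0.0892, adjusted p = 1) against 4.19% over all genes. With equal numbers of peaks per library its net share was 0% (permutation p = 1), and with stricter peaks 5.88% (permutation p = 0.91).

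**Figure D5:**
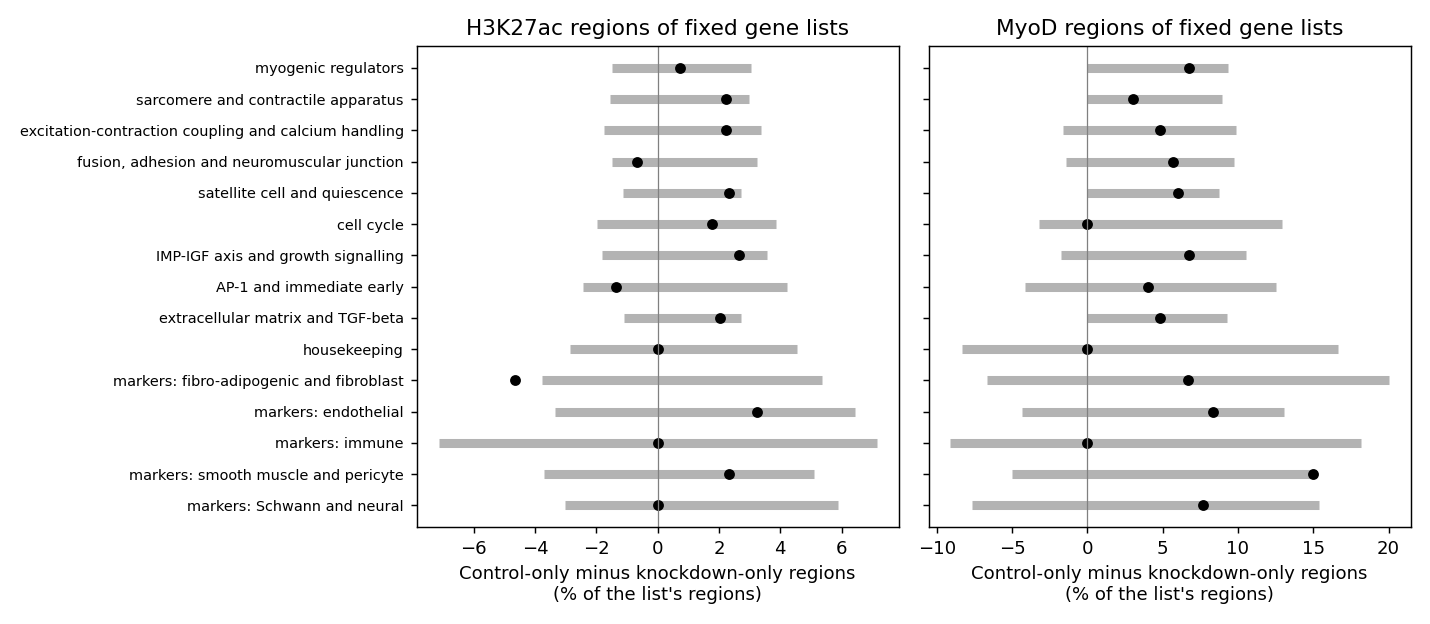
Points give the net share of each of the 15 gene lists, control-only minus knockdown-only regions as a percentage of the list's regions (horizontal axis), for H3K27ac (left) and MyoD (right), and gray bars the central 95% of 10000 matched random lists. The only point outside its bar is that of the fibro-adipogenic markers for H3K27ac, at −4.65%, a list that stood at 7.41% with equal numbers of peaks per library.

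The last comparison asked whether MyoD and H3K27ac were lost at the same places. Among MyoD regions missing from both knockdown libraries, 12 overlapped a control-only H3K27ac region and 548 an H3K27ac region of all 4 libraries; among MyoD regions kept in all libraries the numbers were 44 and 7577. The odds ratio was 3.77 (95% interval 1.98 to 7.18, Fisher's exact p = 0.000324) and 2.54 when stratified by MyoD fold enrichment. Of the 12 shared sites, named after their values were seen, 10 were assigned to a gene. They lay inside Eipr1, Coa8, Pde10a, Stard9, Kif24, Patj, Disc1 and Aagab and near Acyp2 and Bcl7c. At Kif24, which encodes a kinesin, the MyoD fold enrichment was 4.63 and 3.51 and that of H3K27ac 5.21 and 4.73 in the controls. For the mixed pair of control 2 and knockdown 1 the same odds ratio was 1.80 (95% interval 1.09 to 2.99).

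MyoD sites differed in how often they lay in acetylated chromatin. Of MyoD regions present in all 4 libraries, 82.3% and 83.8% overlapped an H3K27ac peak of the control libraries, and 86.6% and 74.9% one of the knockdown libraries. For control-only MyoD regions the shares were 56.6%, 58.0%, 60.7% and 44.2%, and for knockdown-only regions 46.33%, 49.7%, 55.9% and 38.4%. In each of these sets the knockdown 1 library had the highest and the knockdown 2 library the lowest share, the order of their H3K27ac peak numbers.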

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

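Leaving out libraries for the share near gene ends, and assigning regions to the nearest gene end, were alternatives chosen after seeing the data. In the gene list tests 0 lists passed for either antibody under every alternative run. The joint loss odds ratio stayed above 1, from 2.08 to 4.05, and the MyoD share near gene ends stayed higher in control-only regions under every alternative. The H3K27ac peak number difference of −2630.5 was 227 with a fold enrichment of at least 5 and ranged from −9689.5 to 4428.5 when libraries were left out; it was 764 without control 2 and 4428.5 without knockdown 2, and the cause was not tested. The MyoD difference of −2898.5 ranged from −4587.5 to −1209.5 when libraries were left out. It was −942.5 with a fold enrichment of at least 5, a cut that does not ask for the same signal in each list. H3K27ac control-only and knockdown-only regions numbered 387 and 274 with a −log10 q of at least 5 in all libraries, 68 and 42 with it in the group alone, and 495 and 259 when merged within 1000 bp, and knockdown-only regions numbered 712 with equal numbers of peaks. MyoD control-only and knockdown-only regions numbered 518 and 68 with a −log10 q of at least 5 in the group alone, and 498 and 378 with equal numbers of peaks. Leaving out a library sets 1 library against 2, which raises these counts by construction: 970 to 8658 control-only and 956 to 10128 knockdown-only regions for H3K27ac, and 1778 to 3515 and 509 to 2032 for MyoD. The same construction sets regions of 1 library against regions shared by 2 in the shares near gene ends, so these values do not show that a difference depends on a library: between control-only and knockdown-only H3K27ac regions the share differed by −4.39 to 12.4 percentage points, with −4.39 without control 1, 3.51 without control 2 and 12.4 without knockdown 1. That of MyoD ranged from 2.79 to 10.1 points when libraries were left out, with 2.79 without control 2, and was 10.9 within 2 kb of a gene end. Of the 40 named regions, 34 were still group-only with stricter peaks and 33 when merged within 1000 bp. All 40 were so with equal numbers of peaks, which tests little. Cutting the lists adds no peak to the other group, and the named regions were chosen for high fold enrichment. The 3 motif alternatives were not run.

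With the replicate block, the paired differences in peak number, knockdown minus control, were 7823 and −13084 for H3K27ac (mean −2630.5, exact sign-flip p = 1) and −1294 and −4503 for MyoD (mean −2898.5, exact sign-flip p = 0.5, the smallest this pairing allows). Neither the paired nor the unpaired exact test could reach 0.05, so the block could change no call. Over regions, the correlation of same-numbered libraries' deviations was 0.0531 for H3K27ac and 0.0581 for MyoD, under the level of 0.1 set for taking the numbers as pairs. The split with the most exclusive regions differed between lists: for H3K27ac it was the crossed pairs as deposited (3698 against 2348 for same-numbered pairs) and the same-numbered pairs with equal numbers of peaks (1856 against 1630 for crossed pairs), and for MyoD the same-numbered pairs as deposited (1355 against 1283 for control and knockdown) and with equal numbers (1104 against 876) but control and knockdown with stricter peaks (1206 against 1165). Without read counts, a missing peak cannot be told from 1 just under the caller's threshold.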

Other observations

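The strongest MyoD regions present in all 4 libraries were ranked by the mean of their within-list fold ranks and looked up after the comparisons above. The first was in Olfml2b, which encodes an extracellular matrix protein (chromosome 1, 170655290 to 170656393), with fold enrichments of 48.2 and 46.7 in the controls and 49.4 and 43.9 in the knockdown. Others of the first 20 lay in Mamstr, a coactivator of MEF2 factors (36.0, 31.8, 40.5 and 31.7) and in the satellite cell gene Megf10 (31.1, 35.4, 34.5 and 26.0). Zfp568 held the highest-ranked H3K27ac region (chromosome 7, 30003297 to 30014833) and, within it, a MyoD region (30009234 to 30010270) with fold enrichments of 32.1, 30.8, 31.9 and 32.1. The acetylcholine receptor gene Chrna1 and the brain creatine kinase gene Ckb were also among the first 20 H3K27ac regions, with 24.9, 29.9, 26.9 and 23.6 at Chrna1.

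Broad H3K27ac regions of all 4 libraries held MyoD more often than narrow ones, a count also made after the comparisons above, like the shares by gene list that follow it. MyoD regions of all 4 libraries overlapped 57.9% of the broadest width decile (median 4792 bp) and 16.1% of the narrowest, with the lowest share, 13.2%, in the ninth; a broader region has more room for a MyoD site, and width was not adjusted for. The broadest merged regions lay over Hoxc10 (42.6 kb, 0 MyoD regions), Myh9, non-muscle myosin (39.9 kb, 3), Nfix, a fetal myogenic regulator (34.9 kb, 0), and Pmepa1 (32.6 kb, 2). These widths come from peaks joined across libraries, as the widest single H3K27ac peak in any list was 30296 bp. The region assigned to Jph2 (25.5 kb) held 3 MyoD regions and that assigned to Gapdh (23.6 kb) held 7. Such a broad region can span further genes, so its MyoD regions need not belong to the gene named. By gene list, 67.1% of MyoD regions of fusion and neuromuscular junction genes and 62.6% of those of sarcomere genes were present in all 4 libraries, against medians of 43.7% and 43.0% in matched random lists (permutation test, adjusted p = 0.003 for each). For H3K27ac the AP-1 and immediate early genes stood highest, at 61.6% against 42.9% (permutation test, adjusted p = 0.012). In the permutation test none of these 3 differences passed when regions were compared within deciles of fold enrichment (adjusted p = 0.97 for sarcomere genes, 0.346 for fusion genes and 0.97 for AP-1 genes).

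Of the tests that follow, those of list length and of strong sites for the excess of control-only MyoD regions, and that of weak sites for the joint loss, were chosen after the result was seen, as were the finer strata and the use of intervals in both joint loss tests.

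Control-only MyoD regions outnumbered knockdown-only ones 6.25 to 1. Complete loss of MyoD from strongly bound sites would remove regions of high enrichment, but 0.0544% of the regions in the upper 2 quintiles of control fold enrichment were missing from both knockdown libraries; a partial loss there would leave the peaks called and is not excluded. With equal numbers of peaks per library the ratio was 1.32. Equal totals draw the 2 counts together whatever made the lists differ in length. This ratio therefore shows that the excess goes with list length, and does not tell why the lists differ. The implied background pileup, an indirect value related to depth, fell in the order of peak number for MyoD. It was 2.03 in control 1, 2.02 in control 2, 1.71 in knockdown 1 and 1.55 in knockdown 2. In the H3K27ac libraries with a value it did not follow peak number. There it was 4.38 in control 1 with 46259 peaks, 2.38 in control 2 with 53048 and 4.497 in knockdown 1 with 54082. The order seen for MyoD therefore does not show that depth set the length of the lists. Whether the MyoD knockdown lists are shorter because of depth or because of weaker binding across sites after the knockdown was not tested and stays open.

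Control-only MyoD regions lay near gene ends more often than knockdown-only ones. List length as the whole cause is argued against by the difference of 7.11 percentage points (95% interval 2.78 to 11.4) that was left with equal numbers of peaks. Among regions held by 1 library alone, 10.9% and 13.4% lay near gene ends in the controls and 8.06% and 7.002% in the knockdown, so that the lowest control was 2.83 points above the highest knockdown library. A property of each control library may therefore contribute. The share was also lower where knockdown 1 held the region with a control (10.9% and 9.88%) than where knockdown 2 did (14.2% and 15.2%), so a property of the knockdown 1 library stays open as well. A biological difference between the groups would also place both controls above both knockdown libraries, and was not separated from a property of the libraries. By itself it would not set knockdown 1 apart from knockdown 2 if LncMyoD was depleted alike in both, which was not checked.

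MyoD and H3K27ac were lost at the same sites more often than the margins give, with an odds ratio of 3.77. Weak sites are lost more easily for both marks. Over 5 strata of MyoD fold enrichment the odds ratio was 2.54 (95% bootstrap interval 1.08 to 6.41, 2000 resamples), but over 20 strata it was 2.19 (0.854 to 5.32), so weak sites as the cause cannot be told apart from a shared loss with 12 sites. The largest odds ratio over the 4 mixed pairings was 1.80 (1.09 to 2.99), whose interval overlaps that of the real comparison, so co-variation of sites between libraries whatever their group stays open as well. A linked loss of MyoD and acetylation after LncMyoD depletion is a hypothesis that these 12 sites may reflect and do not settle.

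An unplaced contig, Un_JH584304, held 40 and 41 MyoD peaks in the controls and 43 and 41 in the knockdown, against 0 or 1 H3K27ac peaks in each library.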
